A study of Mus musculus with 10 samples.

How the data were processed

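ATAC-seq was run on 10 libraries of mouse neural stem cell lines. Per the labels' protocols, the lines were made from floxed Smchd1 embryos, given a retrovirus with Cre and a puromycin marker, selected with puromycin from 24 h and harvested at 7 days. The same protocol text stands with all 10 samples, and whether control cells received a vector is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, Trim Galore 0.4.0, Bowtie2 2.2.5, SAMtools, Picard, MACS2 and edgeR were named with the build mm10, without the role of each.

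Per the file headers, MACS 2.1.0.20140616 called peaks on 1 pooled alignment per group with no control sample, a shift of 75 bp upstream, an extension of 150 bp and a q-value limit of 0.05. The pooling is read from those headers, which name 1 alignment for each group. Peak pileup is a signal height that the authors deposited with each peak, and it reached at most 300 in every list, since 1 tag per position was kept. Fold enrichment is the authors' own ratio of a peak over the local background. The deposited −log10 p and −log10 q values are also the authors' own. These values were used to describe, rank or filter peaks within a list. Tags used after filtering numbered 144613215 in control females, 139318421 in deleted females, 91734730 in control males and 74674218 in deleted males, and the tag size in the headers was 53, 63, 62 and 59 bp. Depth and read length therefore differed between the groups compared, and weak peaks are less reliable in the male lists.

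Peaks on chromosomes 1 to 19, X and Y were kept. Overlap meant at least 1 shared base pair. Each list was reduced to the 88159 peaks with the highest −log10 q, the length of the shortest list. Peaks present in both sexes' changed sets were counted by overlap, beside the number expected from independent sets over the peaks strong in both sexes. Ratios of peak numbers carry exact binomial intervals, and no p-value was computed, since each group has 1 list. Gene lists used the gene body and 5 kb on each side, each peak counted once, in a RefSeq table of the assembly GRCm38.p6, the same sequence build as mm10. All 258 genes asked for by name were found in it. That table has no strand and no transcripts, so the planned promoter windows were replaced by 1 kb around either end of a gene. The mean difference per gene of each list was placed among 10000 random lists of the same size and similar peak number. These percentiles describe the lists, are not p-values and run high for clusters, whose neighbouring genes share peaks.

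Genes were named by a rule set before the data were examined. It takes the 12 strongest lost and gained peaks in females, the 12 with the best mean rank in both sexes, the 5 strongest in males, the 8 strongest on X in females, Smchd1 and Xist, list members with an end peak changed in both sexes, and up to 4 members per list. Of the peaks lost in males that the rule takes, 1 is not reported here. A peak was given to a gene with an end within 1 kb, else the gene that holds its summit, else the nearest gene end within 50 kb. Firre and Dxz4 are members of a list set before the data were examined. Motif shares for 10 motifs were planned and not run, because no genome sequence was used here.

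The calling of lost and gained peaks was tested on simulated data for the female comparison, with 130103 peaks and noise in strength as between the control lists. With 200 lost and 200 gained peaks it recovered 190 and 188. Each of these peaks was removed altogether from 1 of the lists. The recovery was therefore largely set by the design and says nothing about peaks that only weaken. With no change the rule called 0 and 0. That is no background value for these data, since the simulation varied strength alone on 1 set of peaks. On real lists of 1 genotype the same rule called 85 autosomal peaks between control females and males and 526 between deleted females and males. The alternatives tried were another overlap, list length, margin, strength, ranking value and threshold, and the flank and window of genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.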

Results

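Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in mouse neural stem cell lines of the C57BL/6 strain. The lines came from E14.5 embryos that carried floxed alleles of Smchd1, a chromatin protein needed for silencing on the inactive X chromosome. The groups were 3 control and 3 deleted female libraries, and 2 control and 2 deleted male libraries. Each group was represented by 1 peak list called on its pooled libraries, so no value has a replicate error and no difference was tested between replicates. The lists rested on 144613215 tags in control females, 139318421 in deleted females, 91734730 in control males and 74674218 in deleted males. They held 130487, 104716, 101635 and 88438 peaks in that order. Because the lists differed in depth and in length, comparisons used the 88159 strongest peaks of each list, by the authors' −log10 q. A peak was called lost when it was among the 44079 strongest of the control list and overlapped none of the 88159 strongest of the deleted list, and gained in the reverse case. Intervals are 95% exact binomial intervals and cover counting error only. For ratios they treat the counts of both lists as independent, although the lists share most of their peaks.

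The Smchd1 gene, on chromosome 17 from 71344489 to 71475366 (mm10), had a peak at its end near 71475366 in all 4 lists, with ranks of 597 in control females, 754 in deleted females, 1226 in control males and 271 in deleted males. The deleted part of the gene is not given in the sources used here, so this peak does not check the deletion. Y peaks were used to check the sex labels, since the description of the male samples reads female while their title and sex field read male. The male lists held 112 Y peaks in controls and 104 in deleted cells, of which 41 and 39 were in no female list. The female lists held 98 and 78, of which 23 and 13 were in no male list, so Y peaks separated the sexes in part. Peaks at 2 loci of X, a comparison added after they had been seen, ran as the titles say: Firre had 24 and 21 in the female lists and Dxz4 11 and 7, and each male list had 1 at either locus.

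The first comparison asked how accessibility differed between deleted and control female lines. The strongest peaks absent from the control list lay on chromosome 7 beside Vmn1r71, a vomeronasal receptor gene, and near Zscan4c, a gene known from early embryos. The peak at the Vmn1r71 end, from 10747813 to 10748320, had a fold enrichment of 9.28 in deleted females and no peak in the control list. A peak 20.2 kb from Vmn1r71 ranked 2376 in the deleted list and 100235 in the full control list, and the peak 24.2 kb from Zscan4c, from 11034377 to 11035172, had a fold enrichment of 9.21. On chromosome 5, gained peaks lay 31.5 kb from Tbx5, a T-box transcription factor gene of heart and forelimb, inside Caln1 and inside Tmem132d, with fold enrichments of 7.28, 7.72 and 6.67. Other gained peaks lay at the end of the noncoding gene Gm40331, inside Car10 and 1700081B01Rik, and outside Psg28, 4930503F20Rik and Gm7538. The strongest lost peaks lay inside Lrrtm4, a synaptic adhesion gene, with a fold enrichment of 5.79 in controls, and 32.2 kb from Macc1, with 5.6. Lost peaks also lay inside Myh10, Ckmt2, Ttll7, Mertk, Sema3a, Gmds, Atg10, Homer1 and Rab3c and outside Gm39205. The Myh10 peak had a weaker counterpart at rank 100468 in the deleted list, and the other 11 had none. Of the 12 gained peaks named, 5 had a weaker counterpart in the full control list, those 20.2 kb from Vmn1r71, at Gm40331 and 4930503F20Rik, and inside Caln1 and Car10. The full control list is longer, with 130103 peaks against 104316 in the deleted list, and so offers more counterparts. The 2 tallies cannot be compared.

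In total 499 of 44079 candidate peaks were gained in females, or 1.13% (1.04 to 1.24), and 194 were lost, or 0.44% (0.38 to 0.506). Among the strongest 44079 control peaks 99.6% overlapped the deleted list, and among all 88159 the share was 83.1%. Gained peaks lay at a gene end in 5.41% of cases, against 12.6% of kept peaks of the same rank, and outside genes in 63.1% against 41.7%. The median distance of gained peaks to the nearest end of a protein-coding gene was 92.7 kb, against 37.4 kb for kept peaks of the same rank. Lost peaks lay at a gene end in 4.64% of cases (2.14 to 8.62), about as rarely as gained ones, and outside genes in 38.1%. Their median distance was 35.6 kb. Kept peaks of the same rank were taken for gained peaks only, so the values of lost peaks have no matched comparison. The balance of gained and lost peaks depended on the setting: gained peaks were 72.0% of the changed ones here, 100% among the 22039 strongest peaks, 47.4% without a margin, 42.1% when ranked by pileup, 24.6% with all peaks as deposited and 13.6% at a −log10 q of at least 10. The settings with all peaks as deposited and with the −log10 q threshold do not cut the lists to equal length.

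The same comparison in males gave the same leading sites. The peak 31.4 kb from Tbx5, from 119916518 to 119917209 on chromosome 5, had a fold enrichment of 10.1 in deleted males, and the peak near Zscan4c had 10.4. The peaks at the end of Vmn1r71 and 20.1 kb from it had 11.7 and 9.42, and the peak inside Caln1 had 10.6, each with no peak in the control male list. The strongest lost peaks lay at the end of Gm35562, inside Gm35148, and outside Gm30726 and Gm52338, with control fold enrichments of 6.7 to 7.3. In males 360 peaks were gained, or 0.817% (0.735 to 0.905), and 483 were lost, or 1.1% (1.0 to 1.2). Gained peaks were 42.7% of the changed ones, 100% among the 22039 strongest peaks, 30.4% with all peaks as deposited and 18.1% at a −log10 q of at least 10. The deleted male list was the shallowest, and its peak of rank 88159 had a −log10 q of 1.39, against 4.52 in control males.

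Taking females and males together, 135 peaks were gained in both sexes and 14 were lost in both. Of 38693 peaks strong in both deleted lists, 194 were gained in females and 214 in males, so independent sexes would share 1.07. Of 39743 strong in both control lists, 64 and 138 were lost, so they would share 0.222. Over all 44079 candidates the expected numbers are 4.08 gained and 2.13 lost. All these expected numbers give each strong peak the same chance of being called. Calls were uneven: among the 22039 strongest peaks 0 were lost in either sex, while 57 were gained in females and 26 in males. The expected numbers are thus a low yardstick, and the excess over them does not measure how far the sexes agree. In addition, 1 peak was lost in females and gained in males, and 1 was gained in females and lost in males. Few such opposite cases were possible, so their number says little about agreement of the sexes. Only 57 strong peaks of control females were absent from control males, and 49 the reverse. The gained peaks with the best mean rank were those near Zscan4c, Vmn1r71, Tbx5, Caln1, Gm40331, Tmem132d, Gm7538, 1700081B01Rik, Gm30532 and Gm34052. The peak at the end of Gm40331, from 126787652 to 126788677 on chromosome 5, had fold enrichments of 7.84 in deleted females and 9.16 in deleted males. A peak at the shared end of Snrpn and Snhg14, imprinted genes of chromosome 7, from 60450028 to 60450359, had fold enrichments of 6.24 and 7.73 and no peak in either control list. Among members of the gene lists, Snrpn and Snhg14 alone gained a peak at a gene end in both sexes. Peaks lost in both sexes lay inside Gm4724, Adgrb3, Rab3c, Gm29949, Crb1, Anks1b and Ccdc171, at the ends of Gm34325 and Gm29383, and outside LOC115489615, 6330420H09Rik and Ndst4. Chromosome 7 held 27 of the 135 peaks gained in both sexes and 6.23% of the candidates, and chromosome 5 held 19 and 5.94%. Control females and control males, lines of 1 genotype, differed at 85 autosomal peaks, a number that ranged from 1 to 45908 with the setting. Deleted females and deleted males, also of 1 genotype, differed at 526 by the same rule. Between genotypes, 193 autosomal peaks were lost and 471 gained in females, and 465 were lost and 348 gained in males. Gained peaks were 90.6% of those changed in both sexes, 100% among the 22039 strongest peaks, 52.0% when ranked by pileup, 42.2% without a margin, 15.0% with all peaks as deposited and 8.84% at a −log10 q of at least 10. Several of these sites lie in families of similar genes, where reads can be shared between copies, which was not measured here.

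**Figure D1:**
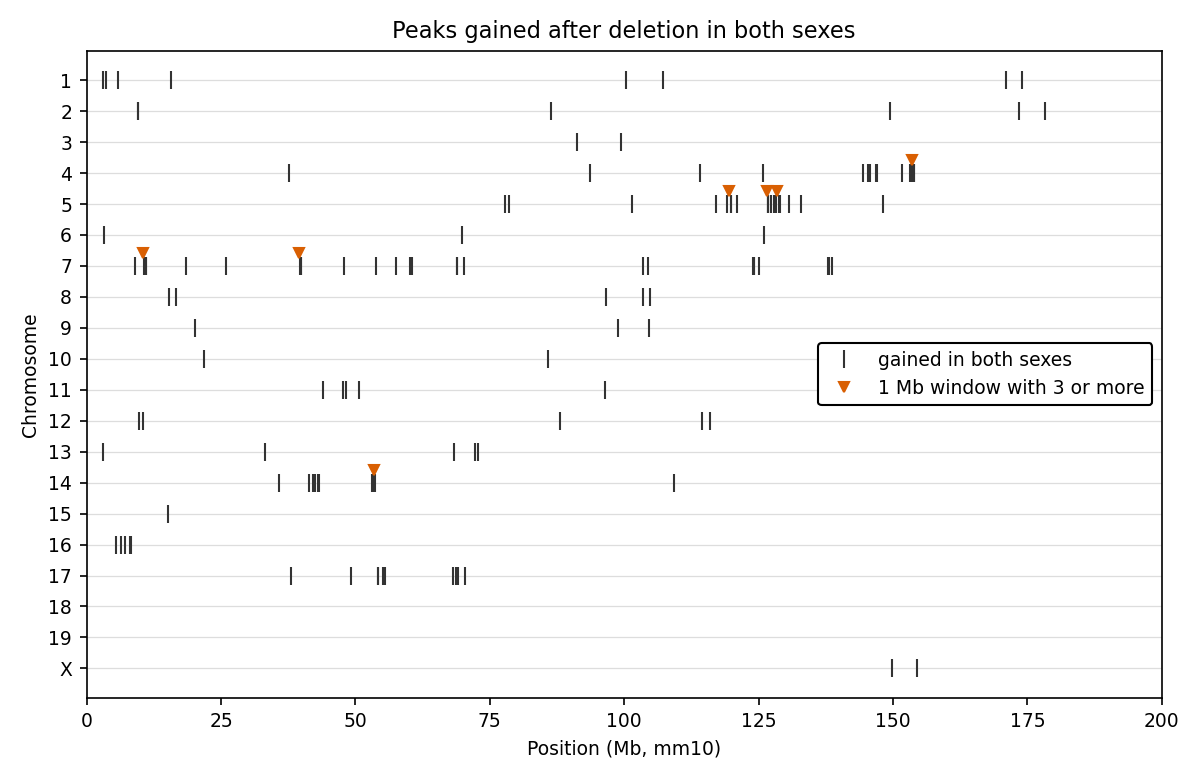
Positions (Mb, mm10) of the 135 peaks gained after deletion in both sexes, 1 tick per peak, with the 20 chromosomes compared as rows and triangles over the 7 windows of 1 Mb that hold 3 or more (grey lines are guides, not chromosome lengths). Chromosome 7 holds 27 of the peaks and chromosome 5 holds 19.

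The X chromosome was compared with the autosomes, since female cells alone carry an inactive X. In females X held 2434 peaks in the control list and 2819 in the deleted list, 1.16-fold more, a log2 ratio of 0.23 (0.15 to 0.31) relative to the autosomes. The autosomes ranged from -0.05 to 0.10, and X stood first of 20 chromosomes. In males X held 2131 and 2040 peaks, a relative log2 ratio of -0.06 (-0.15 to 0.03), within the autosomal range of -0.10 to 0.11. All 18 blocks of 10 Mb along X held more peaks in deleted than in control females, while in males 6 held more, 10 fewer and 2 the same number. The gain in females was uneven: the block from 30 Mb went from 113 to 185 peaks and that from 140 Mb from 168 to 222. The blocks from 70 Mb and 130 Mb went only from 221 to 227 and from 227 to 232. In the 966 protein-coding X genes and 5 kb on each side, peaks went from 1364 to 1468 in females. That is a log2 ratio of 0.106 (-0.001 to 0.213), so most of the difference in X peak number lay away from these genes. Gained X peaks numbered 28 of 1337 in females, or 2.09% (1.4 to 3.01), and lost ones 1 of 1188, or 0.0842% (0.00213 to 0.468), inside Hs6st2. On the female autosomes 1.1% (1.01 to 1.21) were gained and 0.45% (0.389 to 0.518) lost. In males 9 of 1081 X peaks were gained, or 0.833% (0.381 to 1.57), and 18 of 1094 lost, or 1.65% (0.978 to 2.59). The strongest gained X peaks lay at the end of the pseudogene Gm5646, with a fold enrichment of 6.24, and 8.89 kb from Gm22686, with 5.75. The next lay inside Gm42177, E330016L19Rik, Gm15107 and Luzp4 and near Gm15097 and Gm15091, with 4.44 to 4.6. Of these 8, Gm5646, Gm22686 and E330016L19Rik had a weaker counterpart in the full control list. The peaks at Gm5646 and near Gm15091 were gained in males as well, so these 2 are not particular to cells with an inactive X. Around Xist, the noncoding RNA gene that starts X inactivation, the equal-length lists had 3 peaks in control females, 4 in deleted females and 1 in each male list, and the lists as deposited had 4 in both female groups. At Firre, a noncoding repeat locus, control females had 24 peaks and deleted females 21, and at the Dxz4 locus (4933407K13Rik) they had 11 and 7, while each male list had 1 at either locus. The equal-length cut reached a −log10 q of 6.59 in control females and 4.27 in deleted females, so it kept weaker peaks of the deleted list. As deposited, X held 3894 peaks in control and 3412 in deleted females. The relative X ratio was then 0.14, and it was 0.16 at a −log10 q of at least 10. How much of the 0.23 comes from the unequal cut was not tested.

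**Figure D2:**
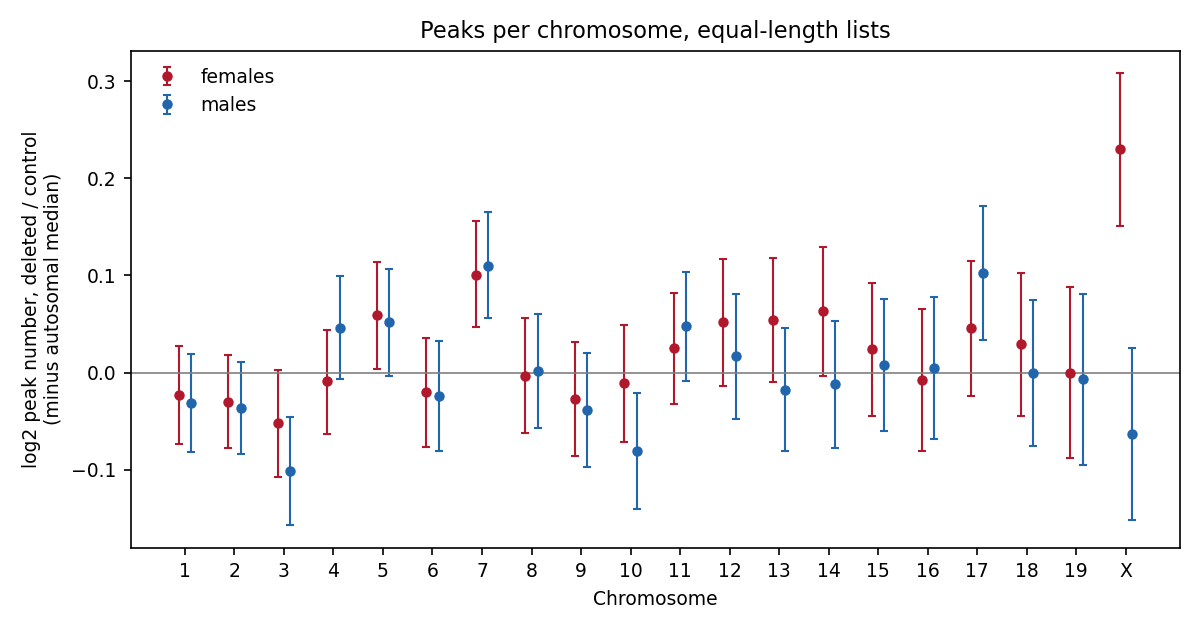
Log2 ratio of peak number in deleted over control lists for each chromosome, minus the autosomal median, with 95% exact binomial intervals for counting error as bars. X lies at 0.23 in females, above every autosome, and at -0.06 in males.

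**Figure D3:**
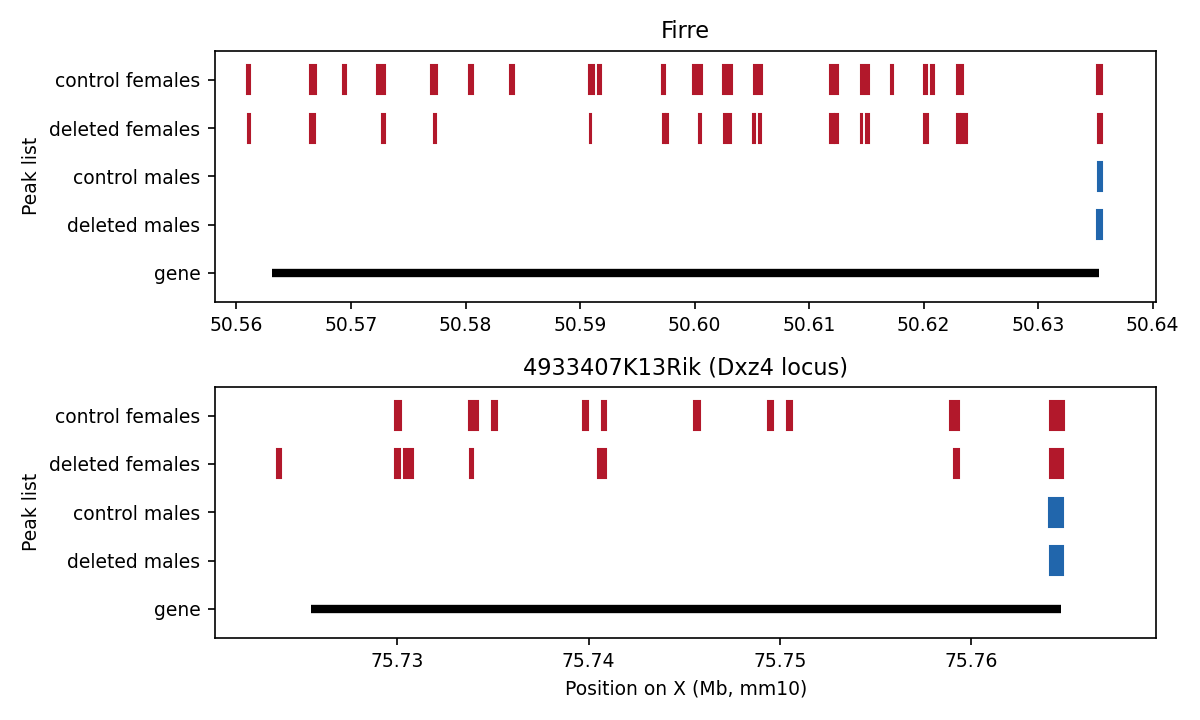
Peaks at Firre and at the Dxz4 locus on X (Mb, mm10) in the 4 equal-length lists, with the gene as a black bar and 5 kb on either side. Control and deleted females have 24 and 21 peaks at Firre and 11 and 7 at Dxz4, and each male list has 1 at each.

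Gene groups fixed in advance were compared by the number of peaks in their genes and 5 kb on each side. In the Snrpn imprinted cluster, peaks numbered 33 in control and 53 in deleted females, a log2 ratio of 0.68 (0.03 to 1.36), and 32 and 49 in males, 0.62 (-0.06 to 1.31). Snhg14, whose span includes Snrpn, went from 23 to 43 peaks in females and from 24 to 40 in males. The Hox clusters, developmental transcription factor genes, had 30 and 40 peaks in females, 0.41 (-0.30 to 1.15), and 25 and 44 in males, 0.82 (0.08 to 1.58). At a −log10 q of at least 10 the female Hox ratio was -0.23 and among the 44079 strongest peaks 0.00, and the male one ranged from 0.49 to 1.81 over the settings tried. Hoxd10 went from 3 to 5 peaks in females and from 1 to 5 in males, Hoxa3 from 3 to 5 and from 1 to 4, and Hoxd11 from 2 to 4 and from 0 to 3, while Hoxb8 went from 2 to 0 and from 3 to 1. The clustered protocadherins, cell adhesion genes of neurons, had 43 and 48 peaks in females, 0.16 (-0.47 to 0.79) but -0.06 at a −log10 q of at least 10, and 30 and 47 in males, 0.65 (-0.04 to 1.36). The male protocadherin ratio was 0.19 at the same threshold and 0.39 among the 44079 strongest peaks. Peaks of the Igf2r imprinted cluster numbered 18 and 19 in females and 15 and 22 in males, and those of other imprinted genes 151 and 161 and 143 and 151. Of the 44 ratios for 22 lists in 2 sexes, 2 had intervals that excluded 0, those of the Snrpn cluster in females and the Hox clusters in males. The nominal number by chance is about 2.2. It decides nothing about these ratios, since the intervals treat peaks shared by both lists as independent counts and some gene lists share genes. Among random lists of the same size, the mean difference per gene stood at percentiles 100 and 100 in females and males for the Snrpn cluster, 99.6 and 100 for the Hox clusters and 98.4 and 100 for the protocadherins, clusters whose genes share peaks.

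Markers of neural stem cells had 60 peaks in control and 64 in deleted females and 69 and 75 in males. Markers of neurons had 67 and 63 and 75 and 67, of astrocytes 31 and 32 and 34 and 29, and of oligodendrocytes 34 and 37 and 34 and 41. Microglia and blood markers had 11 and 13 and 11 and 11, endothelial markers 14 and 15 and 12 and 17, and fibroblast markers 14 and 14 and 17 and 13. Genes that escape X inactivation had 65 and 64 peaks in females and 38 and 34 in males, and the X repeat loci with the inactivation centre had 52 and 47 and 14 and 14. Cohesin and CTCF genes had 34 and 28 and 36 and 33, Polycomb and DNA methylation genes 101 and 95 and 104 and 102, and p53 response genes 36 and 34 and 34 and 35. Interferon response genes had 31 and 38 and 34 and 33, pluripotency and germline genes 9 and 9 and 12 and 12, and housekeeping genes 31 and 28 and 36 and 34. The 1110 olfactory receptor genes, listed as a background for peaks, had 99 and 114 and 91 and 100. The 966 protein-coding X genes had 1364 and 1468 peaks in females, 0.11 (-0.00 to 0.21), and 1264 and 1211 in males, -0.06 (-0.18 to 0.05), at percentiles 100 and 0.4. Percentiles in females and males were 98.42 and 26.91 for interferon response genes and 70.75 and 97.2 for endothelial markers. They were 54.0 and 1.94 for fibroblast markers and 22.94 and 3.92 for neuron markers. None of the intervals of these lists excluded 0, and many of their ratios changed sign with the setting.

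**Figure D4:**
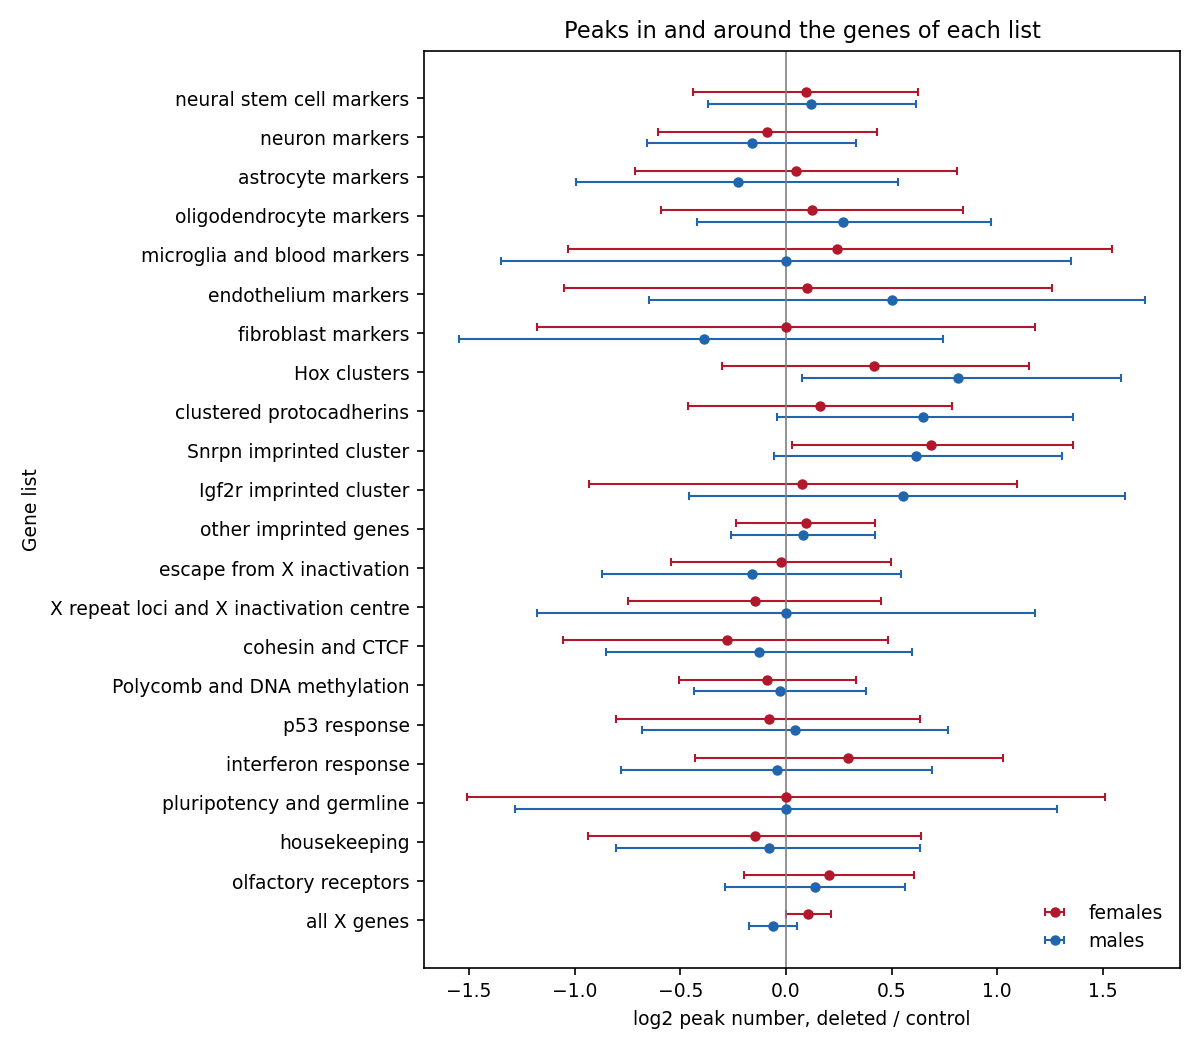
Log2 ratio of peak number in deleted over control lists for the 22 gene lists in each sex, with 95% exact binomial intervals for counting error as bars. The Snrpn cluster in females, at 0.68, and the Hox clusters in males, at 0.82, have intervals that exclude 0.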

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

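The tests of X copy number, read length and the vector cassette were chosen after the results they measure had been seen. The female X ratio exceeded the male one by 0.29 on the log2 scale, a difference that was not tested, where the same difference ranged from -0.06 to 0.08 over the autosomes.

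For the larger number of X peaks in deleted females in the equal-length lists, 5 tests of 4 technical explanations were run. The unequal strength of the female lists at the cut was not among them. A trend with gene density is argued against, since X lay 5.74 residual SD from the autosomes' line, and so is a single block of X, since the lowest value with a 10 Mb block left out was 0.20, above the highest autosome at 0.10. Fewer X copies in the control pool stays open after 2 tests: the first met its bound by sign and was at first read as excluding this explanation, but the second test and a counting interval for the first, both added after that value was seen, left it open. Control females had 7 more Firre and Dxz4 peaks than deleted females (35 and 28, log2 ratio interval -1.09 to 0.44), and the 24 such peaks shared by the female lists had a median log2 rank shift of -0.11 (-0.47 to 0.02). Read length also stays open, with a Y ratio in males of 0.34 (-0.09 to 0.78), and opening of the inactive X after loss of Smchd1 is a hypothesis that stays open beside them, untested because reads were not assigned to either X.

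The peaks gained in both sexes lay close together, with 24 of 135 in 7 windows of 1 Mb that held 3 or more. Chance placement over all strong peaks is argued against, since the highest of 1000 draws was 9. The draws took strong peaks of the deleted female list at any place. Of the peaks gained in both sexes 62.2% lay outside genes, against 27.8% of kept peaks in females. Chance among peaks of such places was therefore not tested. More DNA copies of those windows cannot be told apart from a chromatin change: the other peaks there had median log2 rank shifts of 0.41 in females (bootstrap interval 0.29 to 0.60) and 0.27 in males (0.09 to 0.37). Both medians stood at percentile 100 of random sets of shared peaks, which is part of what this explanation predicted. The windows were chosen for gained peaks in these same lists, however, and the 99 and 86 other peaks sit in only 7 windows. The percentile therefore lends no weight to the explanation. The medians over the autosomes were -0.03 in females and -0.01 in males. Both window medians lie under the bound of 0.5 set in advance against this explanation, but the female interval, computed after the medians were seen, includes it. A response to Cre, the vector or puromycin, which could be shared by both sexes, was not tested. The window with the most gained peaks, 5, starts at 53 Mb on chromosome 14, among V segments of the T-cell receptor alpha locus. Reads shared between such similar segments, which could add to the closeness of peaks, were not measured.

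The peak at the end of Pgk1 moved from rank 2481 to 274 in females and from 1109 to 56 in males, shifts at percentiles 99.96 and 99.99 of the shared strong peaks. The peak at the end of Hprt, another housekeeping gene of X, lay at 1.93 and 6.62. Reads from a selection cassette with a Pgk1 promoter may be a source, but Pgk1 was singled out for this shift and the promoter of the vector is not given in the sources used here, so the test decides nothing. No biological explanation was tested.

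Female lists held Y peaks, 98 in controls and 78 in deleted cells, of which 75 and 65 overlapped a Y peak of a male list. Peaks on other contigs numbered 384 in control females, 400 in deleted females, 313 in control males and 279 in deleted males.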

How the results depend on the processing

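Leaving out blocks of X, leaving out chromosomes 5 and 7, and counting list peaks in the strongest 44079 were chosen after the data had been seen. No paired analysis was possible because each list pools the libraries of its group, and no library could be left out for the same reason. Of 82 alternative values for the main results 23 stayed within 1.5 times the count or the counting interval and 59 moved. Counts cannot change sign, but the balance did: gained peaks were 90.6% of those changed in both sexes and 42.2%, 15.0% and 8.84% without a margin, as deposited and at a −log10 q of at least 10. Values below follow the order lost and gained in females, lost and gained in males, lost and gained in both sexes, and differing between control sexes. With a reciprocal overlap of 50% they were 1743, 2144, 2158, 2147, 290, 455 and 2737, without a margin 14924, 13462, 16459, 14845, 4195, 3067 and 21680, and with the 22039 strongest peaks 0, 57, 0, 26, 0, 16 and 1. At a −log10 q of at least 10 they were 17790, 2791, 12880, 2845, 5395, 523 and 15407, and with all peaks as deposited 40555, 13226, 25812, 11275, 8595, 1519 and 45908. Ranking by fold enrichment moved the lost peaks to 439 in females, 822 in males and 42 in both, and the control difference to 170. Ranking by pileup gave 755 lost in females, 799 lost and 542 gained in males, 108 lost in both and a control difference of 697. With absence judged on the full list 298 peaks were gained in females, 89 in both sexes, and 53 differed between controls. Without chromosomes 5 and 7, 89 were gained in both sexes. Overlap in females and males was 78.2% and 75.8% with the reciprocal overlap, 100% and 100% for the 22039 strongest, 82.2% and 80.3% ranked by fold enrichment, 73.8% and 77.3% at a −log10 q of at least 10, and 68.8% and 74.5% as deposited. The X ratio in females was 0.14 as deposited and 0.16 to 0.25 under the other settings. With all peaks as deposited and at a −log10 q of at least 10 the lists were not cut to equal length. As deposited, the control lists were longer, with 130487 peaks in females and 101635 in males against 104716 and 88438 in deleted cells. A longer list leaves more peaks unmatched, so the larger lost counts there partly reflect list length. Beyond that the cause was not tested for any of these shifts. Of 176 gene list ratios 174 stayed within the wide counting interval of the main value, yet 41 changed sign. Of 88 counts of gene ends 74 stayed within 1.5 times and 14 moved. Motif shares were not run. The depth of the male lists, 91734730 and 74674218 tags, limits weak peaks there.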

Other observations

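The gene families here were chosen after the peaks had been seen, and their counts describe these lists. Peaks in and around the V segments of the T-cell receptor alpha locus (Trav) on chromosome 14, which are rearranged in T cells, numbered 39 in control and 76 in deleted females, a log2 ratio of 0.96 (0.39 to 1.56), and 33 and 67 in males, 1.02 (0.40 to 1.67). Within 50 kb of these segments lay 6 of the peaks gained in both sexes, where their share of strong peaks gives 0.138, among them peaks at the ends of Trav4d-4, Trav9n-3, Trav4n-4, Trav7-4 and Trav9-1. The immunoglobulin heavy chain V segments (Ighv) had 16 and 30 peaks in females, 0.91 (-0.01 to 1.88), and 24 and 28 in males, 0.22 (-0.62 to 1.07). Zinc finger genes (Zfp) had 984 and 1012 peaks in females and 972 and 1044 in males, and held 3 of the peaks gained in both sexes against 3.67 by share. Reads can be shared between similar V segments, which was not measured here, so these values are uncertain.

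Other peaks gained in both sexes lay inside Rimbp2, Hs3st4, Csmd1 and Rbfox1, inside or near Skint11, Pramel13, Psg28, Serpinb9d and Serpinb3c, members of tandem gene families, and 45.6 kb from Hoxb1. Chromosome 7 had the highest ratio of the autosomes in females, 0.10, and in males, 0.11.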
